A study of Mus musculus with 12 samples.

How the data were processed

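Bulk RNA sequencing of mouse lung was analysed for 12 libraries in 4 groups of 3, labelled Control, ALI, MSC and tpMSC. The series title describes acute lung injury from hypoxia and LPS (lipopolysaccharide), with MSC or tpMSC given as treatments, and all animals are wild type per the labels. Per the labels' protocols, mRNA was selected with oligo(dT) beads from total RNA, the second strand was marked with dUTP, and the libraries were sequenced as read pairs on a NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2, edgeR and the GRCm38 build, without saying which tool did which step. The counting tool, its strand setting and the annotation release are not given in the sources used here.

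The authors deposited a table of 38349 genes that holds a raw read count and an FPKM value for each library, per the file headers. Over 10523 genes with at least 500 counts, the ratio of the deposited count to the deposited FPKM varied by at most 0.0013 (SD, log2) around each gene's and library's scale, so both columns hold the same measurement. No count was seen in any library for 1776 genes. Gene positions in the deposited table equal those of GRCm38 for 633 of 35534 nuclear genes (1.78%), while 87.1% have the same span. For that reason the positions printed are those of GRCm38 (GENCODE M21), matched by Ensembl gene ID, with 35571 IDs matched and 2778 without a match.

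Groups and replicate numbers came from the sample titles. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples, which may be technical. The same replicate number in different groups showed no pairing: over 18 pairs, the correlation of group-centred expression ran from -0.108 to 0.104, and 4 of 12 libraries correlated best with a library of their own number. The plan, fixed before the data were examined, had already left the replicate number out of the reported test as a block.

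Before the data were examined, the comparisons, the alternatives, 41 gene lists and the rule for naming genes were fixed. The plan assumed FPKM with limma and named the edgeR quasi-likelihood test as the choice if the table held counts, and that choice was used. Counts were filtered with filterByExpr, scaled with TMM and fitted with 1 mean per group over all 12 libraries in edgeR 4.0.16 (R 4.3.3), leaving 22915 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were taken from the log2 fold change and its F statistic. The median log2 shift of all genes lay within -0.022 and 0.018 in every comparison, and the median biological coefficient of variation was 0.184. Levels are given as deposited FPKM, mean ± SD over 3 libraries.

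Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with a correlation estimated per list. Member counts are given over all genes tested and, where the result differs, adjusted over the list alone. Where no second count stands beside a list, the count adjusted over the list alone was the same. A pair of lists, plasma cells and lipid-associated macrophages, was added after seeing the data.

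Named genes are, for each of 4 comparisons, up to 10 largest rises and 10 largest falls among genes called, with a mean of at least 1 FPKM in the higher group and no overlap between the 3 libraries of each group. Predicted genes, pseudogenes and immunoglobulin or T cell receptor segments were left out of this part. The rule adds up to 4 members with the smallest p from each list. A fold against a group at 0 in every library is a lower bound, set against a floor of 3 counts over the group. Floors and intervals cover counting error only.

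A gene that changed in ALI and was called in the opposite direction in a treated group against ALI is described as moved back. Because ALI libraries enter both comparisons, 20 data sets without any effect were simulated with the fitted dispersions, to see what the sharing alone gives. Chosen after seeing the data, the ALI libraries were also divided in 6 ways, 1 to one comparison and 2 to the other, and the correlation across genes was recomputed on log2 CPM. Position between Control and ALI was computed per library as the projection of log2 CPM (prior count 2) on the ALI minus Control difference over genes called in that comparison, as a percentage of the mean ALI shift.

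The processing was tested on simulated counts with 200 genes changed by known folds. The share of genes changed 2-fold that was called was 51.5% for ALI against Control, 49.2% for MSC against ALI, 47.8% for tpMSC against ALI and 51.5% for tpMSC against MSC. For changes of 1.5-fold these shares were 15.6%, 24.2%, 21.2% and 21.9%, and for 4-fold 78.1%, 71.9%, 76.9% and 65.2%. Between 2 and 8 unchanged genes were called per comparison. Far fewer genes were changed here than the 9126 called in ALI against Control, and the adjusted p depends on that number. The shares therefore need not hold for the real comparisons. Every comparison was simulated from the same mean and dispersion per gene, so differences between the shares do not rank the comparisons. A list of 20 changed genes was called in each simulation and none of 40 unchanged lists was. Genes were simulated independently of each other, so this result does not cover lists whose genes vary together. The estimated correlation of the interferon-stimulated genes, for instance, was 0.887 in ALI against Control.

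Alternatives fixed in advance were limma on log2(FPKM + 0.1), no filter on low values, median-of-ratios scaling, a fit of the 6 libraries compared only, the replicate number as a block, array weights, a fold of at least 2, an estimated correlation for lists, and leaving out each library in turn. Added after seeing the data were limma on log2(FPKM + 1), robust quasi-likelihood moderation, DESeq2 1.42.0 and a fit without immunoglobulin genes.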

Results

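Gene expression was measured by RNA sequencing of whole mouse lung in 12 libraries, 3 each from uninjured lungs (Control), lungs injured with hypoxia and LPS, a bacterial cell wall component (ALI), and injured lungs treated with MSC or with tpMSC. What distinguishes tpMSC from MSC is not stated in the labels. Libraries held 53083002 to 70209229 counts, and 22915 genes were tested. The first principal component held 37.6% of the variance and the second 13.5%.

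Over the 9126 genes called changed in ALI, each library was placed between Control (0%) and ALI (100%). MSC libraries lay at 61.6% ± 8.6 (SD, n = 3) and tpMSC libraries at 45.4% ± 9.8 (SD, n = 3) of the ALI shift. The difference between tpMSC and MSC of -16.2 points did not pass an exact two-sided permutation test (p = 0.2, where the smallest possible p is 0.1).

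**Figure D1:**
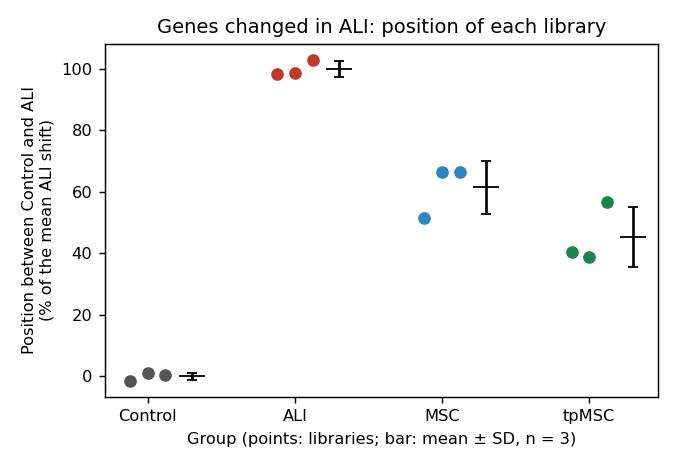
Position of each library between the Control and ALI means, as a percentage of the mean ALI shift over 9126 genes, with points for libraries and bars for mean ± SD (n = 3). MSC libraries lie at 51.6, 66.6 and 66.5%, and tpMSC libraries at 40.6, 38.9 and 56.7%.

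The first question was what the injury changed in the lung. ALI lungs gained transcripts of neutrophils and acute phase proteins. Most cytokine, chemokine and NF-kB genes on the fixed lists rose, and most endothelial and 7 of 12 alveolar macrophage markers fell. Those lists lost their call with an estimated correlation (adjusted p = 0.06 for the inflammatory lists, 0.0935 for endothelium and 0.501 for alveolar macrophages). Saa3, an acute phase protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 0.627 ± 0.136 FPKM in Control to 1475 ± 79.5 in ALI (SD, n = 3 each; log2 fold change 11.25 ± 0.39 SE, adjusted p = 1.96e-08). Acod1, the enzyme that makes itaconate in activated macrophages, rose from 0.04 ± 0.04 to 183 ± 19.3 FPKM. Cxcl5, a chemokine that attracts neutrophils, rose from 0.14 ± 0.052 to 235.9 ± 50 FPKM. Of the largest rises, 7 genes had no count in any Control library, so their folds are lower bounds. Stfa3, a stefin (ENSMUSG00000054905, chromosome 16, 36450537 to 36455392), was at least 969-fold higher in ALI, Prok2 at least 845-fold, Cstdc6 at least 797-fold, Lypd8l at least 290-fold, Saa2 at least 238-fold, Ambp at least 210-fold and Serpina3k at least 197-fold. Among the largest falls, Ear2, a ribonuclease of alveolar macrophages (ENSMUSG00000072596, chromosome 14, 44102654 to 44103534), went from 122.5 ± 12.5 to 4.28 ± 1.25 FPKM (log2 fold change -4.78 ± 0.99 SE, adjusted p = 0.00237). Cyp1a1, a xenobiotic-metabolising oxygenase, went from 15.55 ± 3.86 to 0.213 ± 0.144 FPKM, and Fabp1, a fatty acid carrier, from 11.18 ± 2.29 to 0.19 ± 0.208. Csf2ra, a subunit of the GM-CSF receptor, fell by 6.64 on the log2 scale, Krt79 by 6.53, Zfp1009 by 6.35, Bcan by 5.15, Lipf by 5.05, Krtap17-1 by 4.66 and Asgr1 by 4.66. The call for Asgr1 was lost when ALI replicate 2 or 3 was left out (highest adjusted p over the alternatives 0.0551). With array weights the calls for Csf2ra, Krt79, Zfp1009, Lipf and Lypd8l were lost (adjusted p = 0.275, 0.0647, 0.0763, 0.0508 and 0.0518). Lypd8l, at 2.613 ± 2.9 FPKM in ALI, also lost its call in limma on log2(FPKM + 1), which was chosen after seeing the data (adjusted p = 0.0661). Members of the Stfa and Cstdc family, Saa2 and Saa3, Serpina3k, Ear1 and Ear2, Mrgpra2b and Zfp1009 have close copies in the genome, and how reads were divided among these is not given, so their single values are uncertain.

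**Figure D2:**
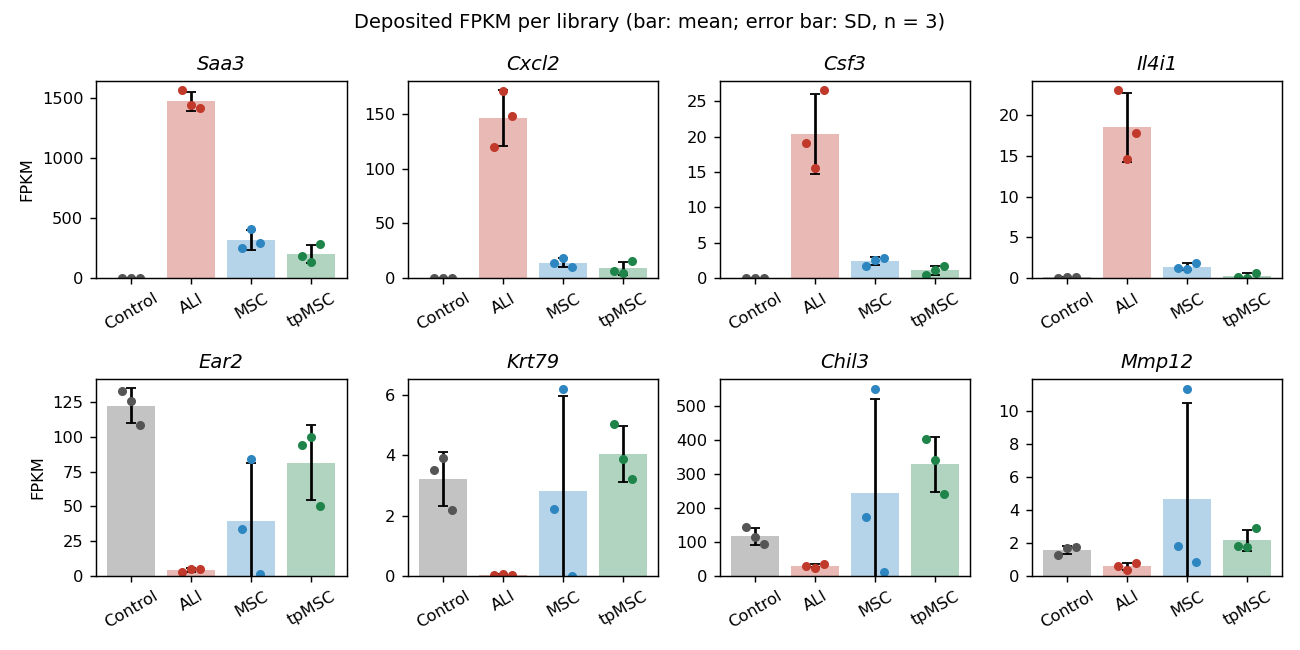
Deposited FPKM of 8 genes in each library, with bars for the group mean, error bars for the SD (n = 3) and points for libraries. Saa3 averages 1475 FPKM in ALI, 319.8 in MSC and 202.1 in tpMSC.

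All 20 neutrophil markers rose in ALI (median log2 fold change 4.33). Trem1, a receptor that amplifies myeloid inflammation, went from 1.51 ± 0.21 to 38.1 ± 3.99 FPKM, and Il1r2, the decoy receptor for interleukin 1, from 0.443 ± 0.0404 to 30.18 ± 1.72. Stfa2l1 reached 120.1 ± 18.1 FPKM and Mrgpra2b 52.13 ± 5.58. The neutrophil list was called with the preset correlation (adjusted p = 1.24e-40) and with an estimated correlation (adjusted p = 0.00225). All 15 acute phase genes rose (median log2 fold change 4.7; adjusted p = 4.73e-46 preset and 0.0023 with an estimated correlation). These were the only lists of the 26 called that also passed with an estimated correlation.

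Inflammatory mediators rose widely. Of 16 cytokine genes, 15 rose, with Il6 at 0.07 ± 0.0436 FPKM in Control and 16.91 ± 4.22 in ALI, Il1b at 9.73 ± 2.53 and 357.8 ± 45.4, and Csf3, the neutrophil growth factor, at 0.0267 ± 0.0306 and 20.37 ± 5.61. Of 21 chemokines, 17 rose and 2 fell. Cxcl13 went from 3.34 ± 0.667 to 476.6 ± 68.9 FPKM, Cxcl2 from 0.227 ± 0.0493 to 146 ± 25.5, Cxcl1 to 230.1 ± 1.78 and Ccl4 to 88.53 ± 9.78. All 18 NF-kB targets rose. Each of these lists was called with the preset correlation, and adjusted p = 0.06 with an estimated correlation for all of them. Of 25 interferon-stimulated genes, 21 rose, such as Irf7 (7.94 ± 0.983 to 32.25 ± 1.22 FPKM) and Ifit3 (32.43 ± 0.898 to 105.3 ± 12.3); adjusted p = 0.501 with an estimated correlation. Of 12 inflammasome and necroptosis genes, 10 rose and 1 fell, with Nlrp3, an inflammasome sensor, at 1.15 ± 0.0971 and 36.06 ± 3.37 FPKM (adjusted p = 0.259 with an estimated correlation).

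Myeloid markers moved in opposite directions. Of 10 monocyte markers, 9 rose, led by Cd14, the LPS co-receptor, from 10.75 ± 1.77 to 430.4 ± 21.8 FPKM (list adjusted p = 0.0935 with an estimated correlation). Of 12 interstitial macrophage markers, 9 rose and 1 fell, with the complement genes C1qa, C1qb and C1qc at 118.2 ± 14.8, 94.9 ± 8.06 and 51.65 ± 2.07 FPKM in ALI (list adjusted p = 0.06 with an estimated correlation). Alveolar macrophage markers fell in 7 of 12 cases and rose in none. Atp6v0d2 went from 19.46 ± 1.92 to 3.09 ± 0.248 FPKM and Siglecf from 6.48 ± 0.218 to 1.19 ± 0.221. That list was called with the preset correlation (adjusted p = 0.00455) and not with an estimated correlation (adjusted p = 0.501). On the alternative macrophage activation list 5 genes rose and 3 fell of 13, with Arg1 up and Mgl2 and Mrc1 down, and the list was not called (adjusted p = 0.782).

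Lymphoid and red cell markers were lower in part. Of 15 T cell markers 8 fell (9 adjusted over the list alone; list adjusted p = 0.532 with an estimated correlation), and of 12 NK and cytotoxic markers 8 fell (9 adjusted over the list alone; list adjusted p = 0.501 with an estimated correlation). Of 10 erythroid genes 8 fell, with Hbb-bt at 2139 ± 721 FPKM in Control and 487.7 ± 17 in ALI (list adjusted p = 0.259 with an estimated correlation). The B cell list was not called (adjusted p = 0.911), with 1 gene up and 1 down of 12, and 1 up and 0 down adjusted over the list alone. Of 10 MHC class II genes 6 rose (7 adjusted over the list alone), without a call for the list (adjusted p = 0.0552). Of 10 dendritic cell markers 1 rose and 3 fell, Clec9a from 15.48 ± 1.55 to 5.25 ± 0.0493 FPKM, without a call (adjusted p = 0.239).

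Endothelial and alveolar type 1 markers fell. Of 20 endothelial markers 17 fell and 1 rose, with Tek, the angiopoietin receptor, from 92.98 ± 4.3 to 28.59 ± 4.84 FPKM and the anticoagulant receptor Thbd from 137.5 ± 0.69 to 49.77 ± 4.33 (list adjusted p = 0.0935 with an estimated correlation). Of 12 alveolar type 1 markers 11 fell and 1, Pdpn, rose from 74.63 ± 5.33 to 149.4 ± 11.4 FPKM (list adjusted p = 0.255 with an estimated correlation). Vegfa, which is on that list and on the hypoxia list, fell from 356.7 ± 11.7 to 168.2 ± 11.1 FPKM. The alveolar type 2 list was not called (adjusted p = 0.777), and its members divided: 5 rose and 6 fell of 15 (5 and 7 adjusted over the list alone), with the surfactant genes Sftpd up from 306.5 ± 7.68 to 844.1 ± 167 and Sftpc down from 11150 ± 461 to 4446 ± 1130 FPKM. Of 12 transitional alveolar markers 9 rose (11 adjusted over the list alone), such as Clu and Cdkn1a (list adjusted p = 0.06 with an estimated correlation). Club and secretory markers divided, 4 up and 5 down of 12 (5 and 5 adjusted over the list alone), with Scgb1a1 from 18070 ± 3750 to 7609 ± 675 FPKM, and the list was not called (adjusted p = 0.326). The ciliated list was not called (adjusted p = 0.135), with 1 up and 2 down of 14 (0 and 2 adjusted over the list alone). Among mesenchymal lists, fibroblast markers had 2 up and 5 down of 12 (3 and 6 adjusted over the list alone; adjusted p = 0.132), with Inmt from 1425 ± 43.2 to 221.7 ± 85.8 FPKM. Smooth muscle and pericyte markers had 4 down of 13 (adjusted p = 0.126). Matrix and fibrosis genes had 11 up and 2 down of 20, with Timp1 from 3.33 ± 0.645 to 215.4 ± 63.9 FPKM (list adjusted p = 0.428 with an estimated correlation).

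Stress and metabolic programs also moved. Of 22 hypoxia targets 16 rose and 2 fell (16 and 3 adjusted over the list alone), with Ldha, Pgk1 and Ndrg1 up; adjusted p = 0.06 with an estimated correlation. Of 14 NRF2 antioxidant genes 10 rose and 2 fell (adjusted p = 0.0564 with an estimated correlation). Of 15 unfolded protein response genes 11 rose and 1 fell, with Hspa5 from 99.03 ± 3.32 to 218.7 ± 21.4 FPKM (adjusted p = 0.349 with an estimated correlation), and of 11 heat shock genes 7 rose (9 adjusted over the list alone; list adjusted p = 0.52 with an estimated correlation). Immediate early genes rose in 9 of 14 cases, with Junb from 27.84 ± 4.28 to 158.2 ± 9.27 FPKM (adjusted p = 0.145 with an estimated correlation). All 25 cell cycle genes rose, Mki67 from 1.94 ± 0.0907 to 8.67 ± 1.67 FPKM (adjusted p = 0.238 with an estimated correlation). Cholesterol synthesis genes had 8 up and 2 down of 18 (adjusted p = 0.569 with an estimated correlation). Glucocorticoid-responsive genes had 4 up and 3 down of 11, with the metallothionein Mt2 up from 4.74 ± 0.188 to 174.3 ± 6.09 FPKM and Klf9 down (adjusted p = 0.255 with an estimated correlation). Clock genes had 11 down and 4 up of 15, and adjusted p = 0.238 with an estimated correlation. Lists that were not called were coagulation and fibrinolysis (7 up, 3 down of 14, and 9 up, 3 down adjusted over the list alone; adjusted p = 0.115), ion and fluid transport (4 up, 2 down of 12, and 4 up, 3 down adjusted over the list alone; adjusted p = 0.343), mesenchymal stromal cell factors (7 up, 4 down of 16; adjusted p = 0.0809), cardiac muscle (1 up of 11; adjusted p = 0.549), skeletal muscle (2 down of 8; adjusted p = 0.29) and adipose tissue (1 up, 1 down of 8; adjusted p = 0.883). Control replicate 3 held more cardiac muscle and adipose transcripts than the other Control libraries, with list scores of 1.96 and 1.16 above the Control mean on the log2 scale. In the club list the median and mean were above 0 (0.09 and 0.58) while the test pointed down, and in the adipose list they were below 0 (-0.35 and -0.52) while the test pointed up.

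In all, 9126 genes changed between ALI and Control, 4630 up and 4496 down, of which 3538 by at least 2-fold (1978 up, 1560 down). With limma on log2(FPKM + 0.1) the balance turned to 3581 up and 4495 down. No overlap between the 3 libraries of each group was seen for 55.9% of genes, where chance gives 10%. Of 41 lists, 26 were called with the preset correlation, 19 up and 7 down, and 2 with an estimated correlation.

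The next comparison asked how injured lungs differed after MSC. MSC lungs had lower transcripts of neutrophils, immediate early genes and acute phase proteins than ALI lungs, and some vascular and airway genes were higher. Most NF-kB targets fell too, but that list lost its call (adjusted p = 0.0842 with an estimated correlation). Trem1 went from 38.1 ± 3.99 FPKM in ALI to 5.84 ± 1.19 in MSC (log2 fold change -2.75 ± 0.18 SE, adjusted p = 2.75e-05), and S100a8, a neutrophil calcium-binding protein, from 947.6 ± 72.3 to 148.6 ± 56.6 FPKM. Prok2 fell by 4.49 on the log2 scale, Mmp10, a matrix protease, by 4.47 and Il4i1, an amino acid oxidase, by 3.73. Ifitm6 went from 48.4 ± 8.3 to 4.47 ± 1.58 FPKM, Cxcl2 from 146 ± 25.5 to 14.26 ± 4.07 and Csf3 from 20.37 ± 5.61 to 2.37 ± 0.558. Stfa3, Mrgpra2b, Ankrd22 and Ambp completed the 10 largest falls. Among the largest rises were Angptl7 (0.29 ± 0.03 to 2.05 ± 0.66 FPKM), Adrb3, a beta-adrenergic receptor (0.473 ± 0.0666 to 1.98 ± 0.914), Nrg2 (0.313 ± 0.0351 to 1.11 ± 0.158), Slurp1 (0.577 ± 0.0802 to 2.25 ± 0.768) and Atp6v0d2 (3.09 ± 0.248 to 20.52 ± 16.6). H3c14, Mmp12, Krt14, Slc6a2 and Tmt1a2 also rose, and each of these calls, like that of Ambp, was lost when at least 1 library was left out; H3c14 has close histone copies. The highest adjusted p over the alternatives was 0.113 for H3c14, 0.135 for Mmp12, 0.167 for Krt14, 0.0899 for Slc6a2, 0.118 for Tmt1a2 and 0.075 for Ambp.

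By list, 16 of 20 neutrophil markers fell (17 adjusted over the list alone; list adjusted p = 0.00177 with an estimated correlation). Immediate early genes fell in 12 of 14 cases, with Junb from 158.2 ± 9.27 to 56.18 ± 4.45 FPKM (list adjusted p = 0.0088 with an estimated correlation). Their list scores in MSC (-0.34, -0.46 and -0.29) lay below the Control libraries (-0.17, 0.23 and -0.06), with 0.6 to 0.92 in ALI. Neutrophil and acute phase scores in MSC stayed above Control. Acute phase genes fell in 10 of 15 cases (15 adjusted over the list alone), with Saa3 from 1475 ± 79.5 to 319.8 ± 83 FPKM, and NRF2 antioxidant genes fell in 6 of 14 (1 up and 10 down adjusted over the list alone), with Osgin1 from 13.28 ± 1.36 to 6.87 ± 0.306. Both of these lists had an adjusted p = 0.0364 with an estimated correlation. NF-kB targets fell in 16 of 18 cases (17 adjusted over the list alone), such as Nfkbia from 220.7 ± 16.8 to 92.83 ± 10.6 FPKM, and cytokines in 9 of 16 (1 up and 11 down adjusted over the list alone), such as Il1b from 357.8 ± 45.4 to 72.02 ± 10.2 and Tnf from 111.7 ± 13.1 to 15.36 ± 1.55. These lists lost their call, with adjusted p = 0.0842 with an estimated correlation for both. Chemokines fell in 8 of 21 cases (1 up and 10 down adjusted over the list alone; list adjusted p = 0.347 with an estimated correlation). Of 10 monocyte markers 2 fell, among them Cd14 (6 adjusted over the list alone; list adjusted p = 0.201 with an estimated correlation). Hypoxia targets fell in 6 of 22 cases (1 up and 9 down adjusted over the list alone), with Ankrd37 from 11.15 ± 2.01 to 3.6 ± 0.572 FPKM (adjusted p = 0.0935 with an estimated correlation). On the mesenchymal stromal cell factor list 6 of 16 genes fell (1 up and 6 down adjusted over the list alone), among them Lif, Ptgs2 and Ptges; its median was 0.07 and its mean -0.29, and adjusted p = 0.412 with an estimated correlation.

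Structural lists moved up in part. Of 20 endothelial markers 6 rose (7 adjusted over the list alone), with Thbd from 49.77 ± 4.33 to 96.61 ± 3.58 FPKM (list adjusted p = 0.347 with an estimated correlation). Of 13 smooth muscle and pericyte markers 7 rose (10 adjusted over the list alone), with the myosin kinase Mylk from 15.05 ± 0.899 to 21.11 ± 1.61 (list adjusted p = 0.0935 with an estimated correlation). The scores of that list in MSC (0.3, 0.51 and 0.2) lay above the Control libraries (-0.08, 0 and 0.08). Fibroblast markers rose in 4 of 12 cases (6 up and 2 down adjusted over the list alone; list adjusted p = 0.347 with an estimated correlation), alveolar type 1 markers in 4 with 1 down of 12 (5 and 1 adjusted over the list alone; list adjusted p = 0.412 with an estimated correlation) and club markers in 3 of 12 (5 adjusted over the list alone), with Aldh1a1 from 83.38 ± 4.29 to 151.6 ± 22.6 FPKM (list adjusted p = 0.529 with an estimated correlation). Clock genes rose in 3 of 15 cases (7 up and 1 down adjusted over the list alone; list adjusted p = 0.201 with an estimated correlation). No cell cycle, T cell, heat shock or unfolded protein response gene on these lists was called. Alveolar macrophage markers rose in 4 of 12 cases (6 adjusted over the list alone; list adjusted p = 0.587 with an estimated correlation), but the libraries differed: the list score stood at -0.59 and 0.59 in MSC replicates 1 and 2 and at -2.44 in MSC replicate 3, below the ALI libraries. Without MSC replicate 3, 6 of 12 rose, with a median log2 fold change of 1.25 in place of 0.92, while without MSC replicate 2 the list lost its call with the preset correlation (adjusted p = 0.244 in place of 0.00282). MSC replicate 3 also held 1.34% of its counts in immunoglobulin genes, against 0.0697 and 0.1035% in the other MSC libraries, and lower cardiac (-0.65) and adipose (-2.19) list scores than the other MSC libraries (2.28 and 2.33, and 1.41 and 0.98).

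MSC lungs differed from ALI lungs in 2347 genes, 1153 up and 1194 down, of which 667 by at least 2-fold (281 up, 386 down); 27% of genes had no overlap, where chance gives 10%. The count was 1221 (425 up, 796 down) in a fit of the 6 libraries compared only. The balance turned to 1396 up and 1039 down with limma on log2(FPKM + 0.1) and, in fits chosen after seeing the data, to 1303 and 1094 with limma on log2(FPKM + 1) and 1847 and 1628 with DESeq2. The count was 3756 with array weights, 1097 without ALI replicate 1, 1252 without ALI replicate 3 and 1084 without MSC replicate 1. Of 41 lists, 25 were called with the preset correlation, 10 up and 15 down, and 4 with an estimated correlation.

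The same question was asked of tpMSC. In tpMSC lungs the neutrophil and acute phase transcripts were lower than in ALI lungs, and smooth muscle transcripts were higher. Most NF-kB and B cell genes on the lists fell, and most alveolar macrophage and endothelial markers rose, but these lists lost their call with an estimated correlation (adjusted p = 0.0566, 0.212, 0.306 and 0.136). Il4i1 went from 18.53 ± 4.24 FPKM in ALI to 0.263 ± 0.318 in tpMSC (log2 fold change -6.09 ± 0.66 SE, adjusted p = 0.000127) and Stfa2 from 107.9 ± 16.1 to 4.01 ± 1.34. Prok2 fell by 6.68 on the log2 scale, Mmp10 by 6.59 (with 4 counts left over the tpMSC libraries), Ambp by 5.05, Stfa3 by 5.02, Cstdc6 by 4.63, Csta3 by 4.48, Csf3 by 4.22 and Cxcl2 by 4.05. Most of the largest rises were in genes that had fallen in ALI. Csf2ra went from 0.103 ± 0.105 to 14.9 ± 7.79 FPKM, Krt79 from 0.03 ± 0.0173 to 4.04 ± 0.932, Ear2 from 4.28 ± 1.25 to 81.33 ± 26.9, Ear1 from 1.88 ± 0.539 to 27.73 ± 7.58 and Fabp1 from 0.19 ± 0.208 to 4.67 ± 2.07. Chil3, a chitinase-like protein of macrophages, went from 29.33 ± 4.72 to 328.9 ± 80.9 FPKM. Lipf, Ccl17, Slc9a4 and Krt14 also rose, while Krt14 and Chil3 were not called in ALI against Control (adjusted p = 0.743 and 0.0855). With array weights the calls for Csf2ra and Krt79 were lost (adjusted p = 0.303 and 0.071). The calls for Ear1, Chil3 and Ccl17 were lost when an ALI library was left out, with highest adjusted p over the alternatives of 0.0541, 0.0572 and 0.0914.

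By list, 19 of 20 neutrophil markers fell, with S100a8 from 947.6 ± 72.3 to 93.36 ± 16.4 FPKM (list adjusted p = 0.00596 with an estimated correlation). All 15 acute phase genes fell, with Lcn2 from 1900 ± 196 to 347.6 ± 126 FPKM, and 9 of 14 NRF2 antioxidant genes fell with 1 up (1 and 10 adjusted over the list alone), with the haem oxygenase Hmox1 from 112 ± 13.9 to 34.27 ± 3.26. Smooth muscle and pericyte markers rose in 11 of 13 cases, with the smooth muscle myosin Myh11 from 5.62 ± 1.45 to 12.34 ± 1.86 FPKM. These lists held with adjusted p = 0.0407 with an estimated correlation. Smooth muscle scores were 0.53, 0.64 and 0.83 in tpMSC replicates 1, 2 and 3, and -0.39 to -0.09 in ALI. The Control libraries scored -0.08, 0 and 0.08, and the list was not called in ALI against Control. The tpMSC scores thus lay above Control, so this rise was not a plain return to Control. Cardiac muscle scores were 0.79, 1.92 and 3.04 in the same tpMSC libraries, and 1.15 to 1.67 in ALI. Whether the smooth muscle rise is linked to cardiac muscle in the samples was not tested. Immediate early genes fell in 10 of 14 cases with 1 up (1 and 11 adjusted over the list alone), and adjusted p = 0.0427 with an estimated correlation. NF-kB targets fell in 17 of 18 cases (list adjusted p = 0.0566 with an estimated correlation) and cytokines in 11 of 16 with 1 up (1 and 12 adjusted over the list alone; list adjusted p = 0.0514 with an estimated correlation). Chemokines fell in 9 of 21 cases with 1 up (1 and 10 adjusted over the list alone), with Cxcl13 from 476.6 ± 68.9 to 47.3 ± 13.7 FPKM (list adjusted p = 0.212 with an estimated correlation). The library tpMSC replicate 3 scored 4.57 on the chemokine list, against 2.82 and 3.06 in the other tpMSC libraries. On the interferon list it scored 2.01, against 0.32 and 0.52. It also scored higher on NF-kB targets (1.6 against 0.7 and 0.7), cytokines (2.68 against 1.43 and 1.38) and monocytes (1.74 against 0.7 and 0.81). Of 25 interferon-stimulated genes 1 fell (list adjusted p = 0.793 with an estimated correlation).

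B cell markers fell in 11 of 12 cases (12 adjusted over the list alone), with Fcer2a from 32.29 ± 1.28 to 4.53 ± 2.28 FPKM and Cd79b from 24.76 ± 3.21 to 8.61 ± 1.17 (list adjusted p = 0.212 with an estimated correlation). The B cell scores of -1.76, -1.9 and -1.31 in tpMSC lay below the Control libraries (-0.49, 0.42 and 0.06), so this fall was not a return to Control. Monocyte markers fell in 6 of 10 cases (8 adjusted over the list alone; list adjusted p = 0.136 with an estimated correlation) and interstitial macrophage markers in 8 of 12 (1 up and 8 down adjusted over the list alone), with Ms4a7 from 15.25 ± 1.13 to 2.2 ± 0.67 FPKM (list adjusted p = 0.212 with an estimated correlation). Alveolar macrophage markers rose in 8 of 12 cases (10 adjusted over the list alone), with Atp6v0d2 at 24.74 ± 3.16 FPKM against 3.09 ± 0.248 in ALI and 19.46 ± 1.92 in Control (list adjusted p = 0.306 with an estimated correlation). Endothelial markers rose in 15 of 20 cases (16 adjusted over the list alone), with Thbd at 132.6 ± 18.4 FPKM (list adjusted p = 0.136 with an estimated correlation). Alveolar type 1 markers rose in 6 of 12 with 1 down (9 and 1 adjusted over the list alone; list adjusted p = 0.306 with an estimated correlation), fibroblast markers in 6 of 12 (6 up and 1 down adjusted over the list alone; list adjusted p = 0.136 with an estimated correlation), club markers in 5 of 12 (6 adjusted over the list alone), with Scgb1a1 from 7609 ± 675 to 18660 ± 4290 FPKM (list adjusted p = 0.39 with an estimated correlation), and ciliated markers in 5 of 14 (7 adjusted over the list alone; list adjusted p = 0.423 with an estimated correlation). Hypoxia targets fell in 9 of 22 cases with 2 up (4 up and 12 down adjusted over the list alone; list adjusted p = 0.136 with an estimated correlation). Heat shock genes rose in 3 of 11 cases (8 adjusted over the list alone), with Hspb1 from 32.98 ± 3.53 to 96.09 ± 31.8 FPKM (list adjusted p = 0.404 with an estimated correlation). Heat shock scores were -0.09 to 0.07 in Control, 1 to 1.16 in ALI and 1.6 to 2.27 in tpMSC, so this rise led away from Control. No cell cycle, T cell or erythroid gene on these lists was called.

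The tpMSC lungs differed from ALI lungs in 5299 genes, 2659 up and 2640 down, of which 1736 by at least 2-fold (681 up, 1055 down); 40.5% of genes had no overlap, where chance gives 10%. The near-even balance turned to 2576 up and 2755 down with median-of-ratios scaling and 2438 and 2601 with the 6 libraries compared only. It was 2514 and 2544 with the replicate number as a block. Without ALI replicate 1 the balance was 1806 up and 1833 down. The remaining fits kept more genes up, such as limma on log2(FPKM + 0.1) with 2723 and 2324. The count was 8444 with array weights, 3458 without tpMSC replicate 1 and 3399 without tpMSC replicate 2. Of 41 lists, 25 were called with the preset correlation, 9 up and 16 down, and 5 with an estimated correlation.

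**Figure D3:**
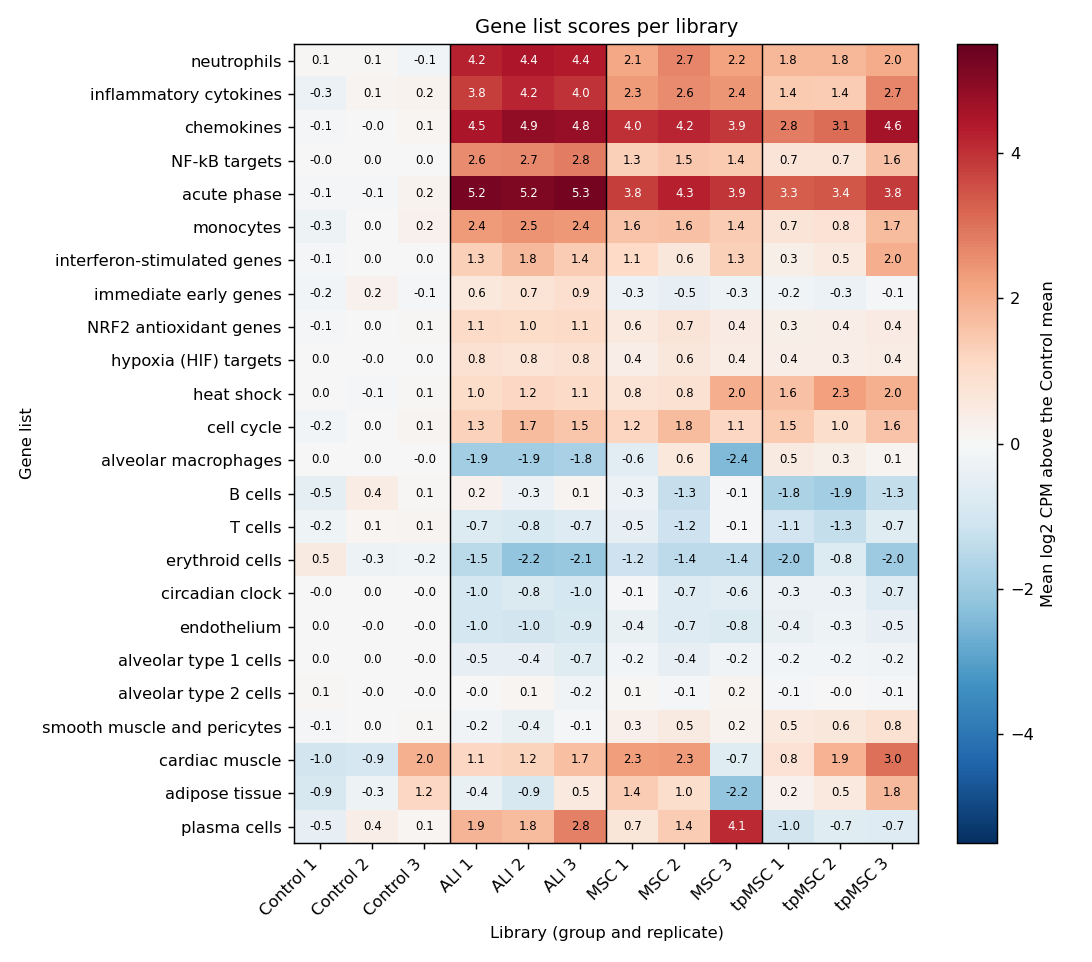
Mean log2 CPM above the Control mean for 24 gene lists (vertical axis) in each of the 12 libraries (horizontal axis), with colour and number giving the score. Neutrophil scores are 4.23 to 4.44 in ALI, 2.11 to 2.69 in MSC and 1.81 to 2.05 in tpMSC, and MSC replicate 3 stands at 4.1 on the plasma cell list.

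How much of the injury response moved back was then counted. Of the 4630 genes that rose in ALI, 1130 (24.4%) fell in MSC and 2115 (45.7%) fell in tpMSC. Of the 4496 genes that fell in ALI, 1081 (24%) rose in MSC and 2168 (48.2%) rose in tpMSC. Whether these shares differ between MSC and tpMSC was not tested, and the direct comparison of the treated groups called 7 genes. Few genes moved further from Control, 3 in MSC and 31 in tpMSC. Of the genes that moved back, 49.5% in MSC and 24.5% in tpMSC still differed from Control. Trem1, at 1.51 ± 0.21 FPKM in Control, stood at 38.1 ± 3.99 in ALI, 5.84 ± 1.19 in MSC and 4.6 ± 1.02 in tpMSC. The same ALI libraries enter both comparisons: simulated data without any effect gave a correlation across genes of -0.503 for MSC and -0.501 for tpMSC, against -0.641 and -0.715 observed, and a covariance of -0.113 for each, against -0.646 and -0.924. With the ALI libraries divided so that none entered both comparisons, in 6 ways chosen after seeing the data, the correlation was -0.529 to -0.402 for MSC and -0.605 to -0.53 for tpMSC. Without that division the same log2 CPM gave -0.694 and -0.742. Genes are not independent replicates. The MSC total of 2211 genes was 1056 without ALI replicate 1, 1185 without ALI replicate 3 and 989 without MSC replicate 1. Both treatments moved many of the same genes: 1053 rose and 1091 fell in both, where independence would give 134 and 138, and 0 genes were called in opposite directions. The shared ALI libraries favour calls in the same direction by themselves, so independence is not the level to expect here. Simulated data without an effect gave a correlation of 0.502 between the treated comparisons, against 0.672 observed. On log2 CPM it was 0.741, and 0.38 to 0.493 with the ALI libraries divided, where no library is shared.

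**Figure D4:**
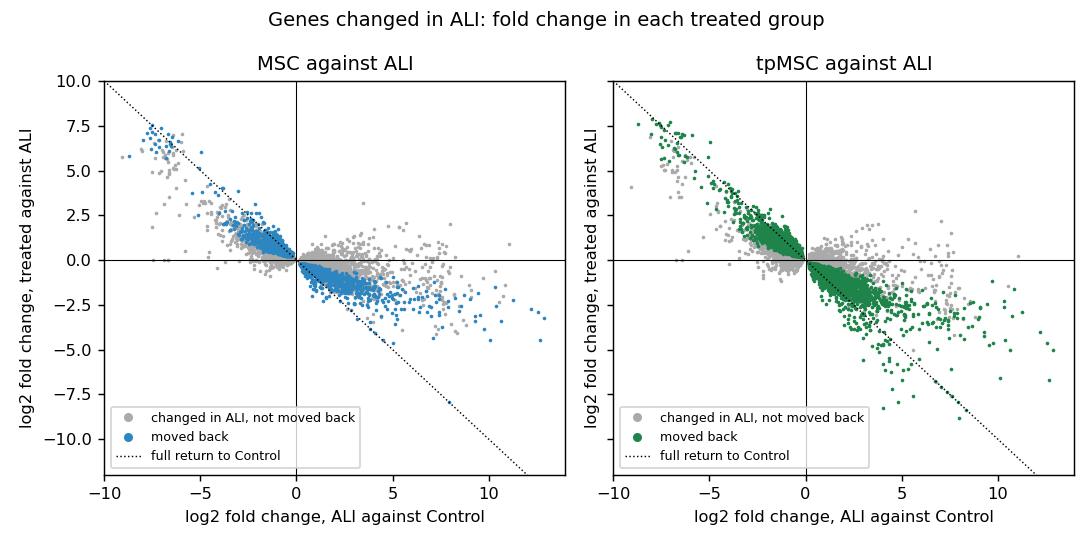
Log2 fold change in ALI against Control (horizontal axis) and in each treated group against ALI (vertical axis) for the 9126 genes changed in ALI, with coloured points for genes that moved back and a dotted line for full return. Coloured points number 2211 for MSC and 4283 for tpMSC.

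The treated groups were then set against each other. In tpMSC lungs Gja4, a gap junction gene of arterial endothelium (ENSMUSG00000050234, chromosome 4, 127311421 to 127314039), stood at 45.22 ± 5.64 FPKM against 27.83 ± 1.42 in MSC (log2 fold change 0.73 ± 0.1 SE, adjusted p = 0.0465), with 30.77 ± 1.96 in Control and 21.08 ± 1.38 in ALI. The BMP targets Id1 and Id3 stood at 75.81 ± 7.77 and 76.3 ± 7.45 FPKM in tpMSC against 48.32 ± 2.3 and 50.32 ± 3.27 in MSC, and Bcl6b at 23.62 ± 2.25 against 15.48 ± 0.803. Pla2g7, a phospholipase of macrophages, was lower in tpMSC (17.92 ± 2.26 FPKM) than in MSC (37.77 ± 7.56; log2 fold change -1.05 ± 0.14 SE, adjusted p = 0.0444). With the immunoglobulin segments Iglv2 and Igkv3-12, both lower in tpMSC and outside the naming rule, these 7 genes were all that edgeR called, while 2893 genes had an unadjusted p under 0.05 and DESeq2, added after seeing the data, called 602. The edgeR count was 0 without immunoglobulin genes, without a filter on low values, with the replicate number as a block and with the 6 libraries alone. It was 4 with median-of-ratios scaling, and 3 at a fold of at least 2. Leaving out 1 library gave 0 to 386 genes: 386 without tpMSC replicate 3, 104 without MSC replicate 1, 52 without MSC replicate 2, 18 without MSC replicate 3, 2 without tpMSC replicate 1, 1 without Control replicate 1 or ALI replicate 3, and 0 without tpMSC replicate 2, Control replicate 2 or 3, or ALI replicate 1. No overlap was seen for 14.2% of genes, where chance gives 10%.

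Of 41 lists, 17 were called between tpMSC and MSC with the preset correlation, 6 up and 11 down, and 0 with an estimated correlation; no member of a list fixed in advance passed over all genes. Adjusted over the list alone, 12 of 12 B cell markers were lower in tpMSC (median log2 fold change -1.15, list adjusted p = 0.297 with an estimated correlation), with Ms4a1 at 1.54 ± 0.62 FPKM against 4.71 ± 2.32. B cell scores were -1.9 to -1.31 in tpMSC and -0.33, -1.28 and -0.08 in MSC replicates 1, 2 and 3. MSC replicate 2 thus lay close to tpMSC, and without MSC replicate 3 the median was -0.92. Adjusted over the list alone, 6 of 12 interstitial macrophage markers were lower (list adjusted p = 0.244 with an estimated correlation), 3 of 20 neutrophil markers lower (adjusted p = 0.297 with an estimated correlation), 5 of 11 heat shock genes higher (adjusted p = 0.309 with an estimated correlation), 4 of 20 endothelial markers higher (adjusted p = 0.297 with an estimated correlation) and 2 of 13 smooth muscle markers higher (adjusted p = 0.244 with an estimated correlation). Heat shock scores were 1.6 to 2.27 in tpMSC, 0.77 and 0.84 in MSC replicates 1 and 2, and 2 in MSC replicate 3; without MSC replicate 3, 5 of 11 heat shock genes passed over all genes, with a median log2 fold change of 0.91 in place of 0.52. On the plasma cell list, added after seeing the data, 0 of 17 genes passed over all genes and 14 were lower adjusted over the list alone, with the MSC mean resting on MSC replicate 3, which scored 4.1 against 0.68 and 1.38. On the lipid-associated macrophage list, also added after seeing the data, 1 of 15 genes passed over all genes and 8 were lower adjusted over the list alone, with Gpnmb at 5.43 ± 1.44 FPKM in tpMSC and 27.66 ± 20 in MSC. Neither added list is independent evidence, since both were chosen on these libraries.

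Against Control, MSC lungs differed in 4284 genes (2451 up, 1833 down) and tpMSC lungs in 3643 (2086 up, 1557 down), with 1500 (1138 up, 362 down) and 1224 (830 up, 394 down) of these by at least 2-fold. For tpMSC the balance turned to 1734 up and 1802 down with limma on log2(FPKM + 0.1), and to 1633 up and 1883 down with limma on log2(FPKM + 1), chosen after seeing the data. The MSC count was 2541 without Control replicate 1 and 2465 without Control replicate 2. The tpMSC count was 5952 with array weights, 1860, 1830 and 2419 without Control replicate 1, 2 and 3, and 2287 without tpMSC replicate 3. Whether the counts for MSC and tpMSC differ was not tested. Saa3 remained at 319.8 ± 83 FPKM in MSC and 202.1 ± 77.6 in tpMSC, against 0.627 ± 0.136 in Control.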

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

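Counts that moved by more than 1.5-fold are given here, and the cause was not tested unless the setting itself has fewer libraries or asks for more. A fold of at least 2 left 3538 genes for ALI against Control, 667 for MSC against ALI, 1736 for tpMSC against ALI, 3 for tpMSC against MSC, 1500 for MSC against Control and 1224 for tpMSC against Control. Array weights gave 3756 for MSC against ALI, 8444 for tpMSC against ALI and 5952 for tpMSC against Control. With the 6 libraries compared only, MSC against ALI had 1221 genes, 34.8% of them up, and tpMSC against MSC had 0. For tpMSC against MSC the count was also 0 without a filter, with the replicate number as a block and without immunoglobulin genes, 4 with median-of-ratios scaling and 602 in DESeq2, the last fit and the one without immunoglobulin genes having been chosen after seeing the data. With an estimated correlation 2, 4, 5 and 0 lists were called in ALI against Control, MSC against ALI, tpMSC against ALI and tpMSC against MSC.

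Leaving out each library in turn gave 7456 to 9460 genes for ALI against Control, 1084 to 2930 for MSC against ALI, 3399 to 5800 for tpMSC against ALI, 0 to 386 for tpMSC against MSC, 2465 to 4751 for MSC against Control and 1830 to 4247 for tpMSC against Control. Lists called ran over 26 to 28, 21 to 32, 25 to 28 and 17 to 24. Genes moved back ran over 989 to 2753 for MSC and 2943 to 4667 for tpMSC. In tpMSC against Control 57.3% of called genes were up, against 49% in limma on log2(FPKM + 0.1) and 46.4% in limma on log2(FPKM + 1), which was chosen after seeing the data. Over the named genes, 14904 of 15710 values kept direction and call, 494 lost the call, 283 gained it and 29 changed sign, 0 of these for a called gene.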

Other observations

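All tests below, the splits of the libraries included, were written down only after the results had been seen.

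The levels of alveolar macrophage markers relative to Control are given as values, and differences between markers were not tested. In MSC 4 of 12 markers rose against ALI and in tpMSC 8, and the list lost its call with an estimated correlation in both (adjusted p = 0.587 and 0.306). Siglecf stood at 18.4% of its Control level in ALI, 22.2% in MSC and 59.5% in tpMSC. Ear2 stood at 3.49%, 32.4% and 66.4%, and Pparg, the receptor that drives alveolar macrophage identity, at 27.3%, 63.7% and 96.1%. Atp6v0d2 stood at 15.9%, 105% and 127%, Chil3 at 25.1%, 210% and 281%, and Fabp4, which was not called in ALI, at 177%, 227% and 191%. MSC replicate 3 scored -2.44 on this list, so the MSC percentages average unlike libraries.

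Clock genes moved as 2 arms in ALI. Bmal1, Npas2, Clock and Cry1 rose, and Dbp, Tef, Hlf, Per3, Nr1d1 and Nr1d2 fell. Dbp stood at 56.6 to 59 FPKM in Control and 3.17 to 4.67 in ALI. It stood at 31, 3.28 and 2.87 in MSC replicates 1, 2 and 3, and at 9.92, 10.1 and 4.74 in tpMSC. Xist was present and Uty had 0 counts in all 12 libraries.

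Over 331 KEGG pathways named in the deposited table, 103, 96, 87 and 49 were called with the preset correlation in ALI against Control, MSC against ALI, tpMSC against ALI and tpMSC against MSC. With an estimated correlation 0 were called in every comparison, with lowest adjusted p of 0.55, 0.594, 0.586 and 0.623.

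The fall of alveolar macrophage markers in ALI could come from dilution by recruited cells. Dilution alone would lower markers of other resident cells by the same amount. The macrophage score minus the alveolar type 2 score was -1.83 (SD 0.24, n = 3) in ALI. The type 2 list divided, with 5 up and 6 down of 15, so its score is no fixed reference. Endothelial scores were -0.99 to -0.88 in ALI, and macrophage scores of -1.93 to -1.77 lay below these too. The values argue against dilution alone for this list score, though neither reference is known to be unaffected by injury. Loss of these macrophages with unchanged expression in the rest would lower all markers alike. The 12 markers spread over 7.42 log2 units, but the share of these transcripts from other cells is not known, so loss cannot be told from altered expression.

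MSC replicate 3 stands apart from the other MSC libraries. A test by distance, run first, put it closer to the ALI mean (0.799) than to the mean of the other MSC libraries (0.822), but none of the 3 MSC libraries lay closest to its own group (8 of 12 libraries did), with MSC replicates 1 and 2 closest to tpMSC. That test was replaced after its result was seen, because an MSC mean without this library rests on 2 libraries. The same holds for the own-group mean of every library, so its result still stands beside the second test. The replacement used the neutrophil score, which was 2.2 in MSC replicate 3 and 4.23 to 4.44 in ALI (SD 0.11). This argues against an ALI library like these 3 under an MSC label. It rests on 1 list score, so an ALI lung with a milder response and other kinds of mix-up are not excluded. Lymphoid tissue taken along with the lung might raise B and T cell scores. The larger difference from the mean of the other MSC libraries was 0.73, for B cells. Those 2 libraries themselves scored -0.33 and -1.28 (SD 0.67, n = 2), so this cannot be told. No biological explanation was tested.

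The clock shift could come from dilution by recruited cells. In ALI the whole clock list score, minus the lower of the alveolar type 2 and endothelial scores, was 0.04 (SD 0.14, n = 3). Its members went both ways, so this mean cannot decide. Earlier forms of this test used only the 4 genes that rose, or the 11 that fell (-0.8, SD 0.18). They were dropped after being seen, because each took genes picked for their direction. Dilution alone would raise no clock gene, yet Bmal1, Npas2, Clock and Cry1 rose (log2 fold change 1.74, 2.39, 0.31 and 1, SE 0.19, 0.36, 0.1 and 0.14). The 6 genes of the Dbp arm had log2 fold changes of -3.89 to -1.52, against endothelial scores of -0.99 to -0.88. For these genes the values argue against dilution alone, but the share of their transcripts from recruited cells is not known. Another hour of collection for ALI lungs would move the arms apart, and 6 of 6 genes of the Dbp arm fell. Hour and injury go with the same libraries, so these cannot be told apart.

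Groups of 3 against 3 give 10 splits, so the share of splits with a count as large is never under 0.1. Every split but the real one mixes libraries of both groups. Where the groups differ, mixing widens the spread within each group and keeps the gene counts low. The gene counts of those splits are therefore not the level expected without an effect. Real counts and the highest other split were 9126 and 1 for ALI against Control, 2347 and 2 for MSC against ALI, 5299 and 0 for tpMSC against ALI, 7 and 3 for tpMSC against MSC, 4284 and 1 for MSC against Control, and 3643 and 0 for tpMSC against Control. For genes moved back they were 2211 and 2 for MSC, and 4283 and 0 for tpMSC. In each of these, 1 of 10 splits, the real one, had a count as large. For lists called with the preset correlation they were 26 and 25 for ALI against Control (1 of 10 splits as large), 25 and 27 for MSC against ALI (2 of 10), 25 and 24 for tpMSC against ALI (1 of 10) and 17 and 21 for tpMSC against MSC (5 of 10). The preset-correlation list counts therefore carry little weight by themselves.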
